A study of Mus musculus with 16 samples.

How the data were processed

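Total RNA of R1 mouse ES cells, 5 iPS lines and 2 types of MEF was measured on 16 MouseWG-6 version 1.1 arrays, 2 per group. Per the labels, the 2 arrays of a group are biological replicates, 500 ng of RNA was labelled for each array and ES and iPS cells grew on MEF feeders. No array was left out.
The deposited raw table holds signal intensity per probe, which the authors exported from BeadStudio 3.2.6 without normalization or error model, per the file headers. Its values run from 22 to 34466 on a linear scale. The deposited detection score is 1 minus a detection p, per the file headers, and the deposited number of beads is given for each probe, with a median of 37 and never fewer than 5. The deposited series matrix holds linear signal intensity that the authors normalized between arrays by a method the labels do not state. Its 46632 probe names could not be paired with those of the raw table, so it was used only as an alternative for counts of probes and for positions. Slides were read from the array names, which give 4 slides.
The raw signal was background-corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, using detection p and an offset of 16, then quantile normalized and put on log2. A probe counted as detected on an array at a detection p under 0.01. Target names were brought to current symbols with the gene table of the mouse reference, 16079 of 34325 by symbol, 6654 by synonym, with 11592 kept as they were. Each gene was represented by its probe with the highest mean over all arrays (9099 genes have more than 1 probe) and kept if that probe was detected on at least 2 arrays. This left 15642 of 32089 genes. The number of arrays limits the precision, since each group has 2 and the fit keeps 8 residual degrees of freedom and gains 6.23 from moderation.
A limma fit with 1 mean per group and all 16 arrays gave 15 contrasts, with moderated t-statistics. A contrast over several lines averaged the lines with equal weight. P values were adjusted by the method of Benjamini and Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. These arrays sample the variation within a line. A fit with 1 mean per line tested the variation between lines. The replicate numbers were checked as pairs: the deviations of the replicates correlated over 0.1 in 27 of 28 pairs of groups, from 0.0984 to 0.430. By the array names the replicate number is also the slide: within each set of groups that share slides, the first and second replicates lie on 2 different slides. As 1 pair fell short of 0.1, the fit has no block, and fits with a replicate block and with a slide block were run as alternatives.
The lists are the reprogramming factors, pluripotency, epithelial junction, fibroblast and matrix, Hox genes, primitive endoderm, trophectoderm, mesoderm and streak, neural and epiblast, germ line, imprinted, Myc targets and ribosome biogenesis, cell cycle, senescence and p53, chromatin regulators, interferon and antigen presentation, glycolysis, oxidative phosphorylation, muscle, endothelium, blood and macrophage, and sex-linked genes. They were written before the data were examined, as were the contrasts, thresholds and the rule for named genes. Each list was tested against all other genes with camera, at a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated for each list. The p values were adjusted over the 22 lists of a contrast. Chromosomes were tested likewise, a choice made after the values were seen, over 12513 genes on the autosomes or X.
Named genes were drawn from a set fixed by rule. For each contrast it holds the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap between the groups, and up to 4 called members of each list with the largest change. It also holds Pou5f1, Sox2, Klf4, Myc, Esrrb and Nanog in every group. Predicted, clone and control names were passed over. Genes of a list are given whether called or not where a count of 5 or fewer is named. A gene not above background on any array of 1 group is given a bound: its level in the other group against its own level or, where higher, the lowest level of any detected probe on the array, which lay between 4.89 and 5.05 on log2 over the arrays.
The axis position of an array is the projection of its difference from the ES mean on the MEF minus ES difference, over genes called between them with at least 4-fold. Correlations are Pearson correlations of log2 values across genes. For changes shared by the 5 lines, all 16 arrays were simulated without change, each gene around 1 mean. The 5 lines share the simulated ES arrays. Other splits of the arrays into groups of the same sizes were run for the 2 contrasts with at least 3 arrays on each side.
Of 200 genes changed 2-fold in simulated data, the fit called 96.5% for OSCK against ES cells and 100% for OSE against OSCE. Of those changed 1.5-fold, it called 32% and 87.5%. Unchanged genes were 1.96% (Esrrb lines against MEFs, 4-fold) to 9.86% (OSCK against ES cells, 1.5-fold) of the calls. Camera called 100 of 100 simulated lists of 30 genes shifted by 0.3 on log2, and 0 of 100 without a shift. Neither test shows how correlated genes, slides or lines affect calls.
The series matrix alternative changes the background correction, the normalization and the unit (probes in place of genes) together. The other alternatives changed 1 choice at a time: no background correction, median centring in place of quantile normalization, no filter or a filter of at least 8 arrays, the mean of detected probes, every probe by itself, a trended and robust moderation, only the compared groups, a replicate block, a slide block, lines as replicates, a 2-fold minimum, an estimated correlation in camera, other axis genes and each array left out in turn. The slide block was fixed where the compared groups share slides and random otherwise, with a consensus correlation of 0.196. A test for arrays that stand apart needs at least 4 arrays in a group and was not run.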

Results

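Gene expression was measured on 16 Illumina MouseWG-6 version 1.1 BeadChip arrays of mouse cells, 2 in each of 8 groups. The groups were R1 embryonic stem (ES) cells, 5 lines of induced pluripotent stem (iPS) cells and 2 types of mouse embryonic fibroblast (MEF). The MEFs carried a green fluorescent protein (GFP) transgene under an Actin promoter or under the Pou5f1 promoter. The iPS lines were named OSCK, OSCE #8, OSCE #13, OSE #T8 and OSE #T9, and are written here without the number sign. In the common use of such names the letters stand for the reprogramming factors Oct4 (Pou5f1), Sox2, c-Myc, Klf4 and Esrrb; the labels do not spell them out. The 4 lines with an E in their name are called Esrrb lines here. ES and iPS cells were grown on mitomycin C-treated MEF feeders with 15% serum and LIF, a cytokine that keeps mouse ES cells undifferentiated, so their RNA can hold feeder RNA. The stated purpose was to compare the Esrrb-reprogrammed lines with ES cells and with MEFs.
Each array detected between 35.5% and 38.8% of 46643 probes, with a median of 37 beads per probe. After a filter on dim probes, 15642 genes were tested. Replicate arrays of a group correlated across genes at r = 0.989 (OSE T9) or more, where genes are not independent replicates. The 2 arrays of a group are called biological replicates of the same line, so each line stands for itself. OSCE 13, OSE T8 and OSE T9 were hybridised on other slides (3 arrays on each of 2 slides) than the ES cells, OSCK, OSCE 8 and the MEFs (5 arrays on each of 2 slides). No slide holds arrays of both sets, so a direct comparison between the sets cannot tell the slide from the group. Groups of 1 set can be compared within a slide. In what follows, a fold change is followed by the log2 difference ± its standard error. A fold given as at least a value is a lower bound, for a gene not above background on any array of the lower group. A list median with bounds sets members below background in 1 group at that bound. Called genes had a limma adjusted p under 0.05. For a list, counts adjusted over the list alone (higher, then lower) use p values adjusted among its members only, and the adjusted p of the list is that of the camera test over 22 lists.

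The comparison of MEFs (n = 4 arrays) with ES cells (n = 2 arrays) measured the distance that reprogramming has to cover. Genes of the pluripotent state were on in ES cells and at or near background in MEFs. The DNA methylation cofactor Dnmt3l (at least 339-fold), the germ and stem cell gene Dppa4 (at least 126-fold), the orphan nuclear receptor Esrrb (at least 119.9-fold) and the transcription factors Nanog (109-fold, -6.77 ± 0.12) and Pou5f1 (107-fold, -6.74 ± 0.14, above background on 1 of 4 MEF arrays) were all lower in MEFs. The neuropeptide gene Trh (at least 248-fold) fell with them. Cell adhesion changed too, since the epithelial adhesion molecule Cdh1 (at least 14.7-fold) and the epithelial splicing factor Esrp1 (at least 14.1-fold) were lower in MEFs. The insulin-like growth factor binding gene Igfbp5 (219-fold, 7.78 ± 0.14), the growth factor gene Ptn (111-fold, 6.80 ± 0.13), the elastic fibre gene Mfap4 (52.8-fold, 5.72 ± 0.14), the matrix proteoglycan Dcn (24.4-fold, 4.61 ± 0.13) and the collagen gene Col1a2 (17.0-fold, 4.08 ± 0.25) were higher. The largest adjusted p of these genes was 1.97e-09. Between MEFs and ES cells, 9539 of 15642 genes were called, 4796 higher and 4743 lower, 3622 of them by at least 2-fold. With 1 mean per line or MEF type as a replicate, limma called 4833 genes.
Of the fixed gene lists, the pluripotency list had 0 higher, 40 lower and 1 not called of 41 (0 and 40 adjusted over the list alone, median -4.49, -3.87 with bounds, adjusted p = 1.12e-25) in MEFs. The reprogramming factors had 0 higher, 5 lower and 1 not called of 6 (0 and 6 adjusted over the list alone, median -5.01, adjusted p = 4.21e-05). the epithelial junction list had 0 higher, 16 lower and 2 not called of 18 (0 and 16 adjusted over the list alone, median -1.87, -1.39 with bounds, adjusted p = 8.92e-08). The fibroblast and matrix list had 45 higher, 1 lower and 3 not called of 49 (45 and 1 adjusted over the list alone, median 1.96, adjusted p = 9.89e-17). Hox genes, which mark position along the body, had 23 higher, 1 lower and 6 not called of 30 (23 and 1 adjusted over the list alone, median 1.103, 0.89 with bounds, adjusted p = 8.92e-08), led by Hoxc8 (9.04-fold, 3.18 ± 0.10). Markers of muscle had 12 higher, 2 lower and 2 not called of 16 (13 and 2 adjusted over the list alone, median 0.86, 0.65 with bounds, adjusted p = 0.0013). Those of blood and macrophages had 15 higher, 1 lower and 3 not called of 19 (15 and 1 adjusted over the list alone, median 1.95, 1.29 with bounds, adjusted p = 9.95e-07), with the lysozyme gene Lyz2 (15.6-fold, 3.96 ± 0.14) and the complement gene C1qc (at least 10.5-fold) the highest. Imprinted genes, expressed from 1 parental copy, had 17 higher, 7 lower and 6 not called of 30 (17 and 7 adjusted over the list alone, median 0.62, 0.31 with bounds, adjusted p = 0.00605), led by H19 (51.4-fold, 5.68 ± 0.17).
Genes of growth were lower in MEFs. The list of Myc targets and ribosome biogenesis had 3 higher, 31 lower and 2 not called of 36 (3 and 31 adjusted over the list alone, median -1.38, adjusted p = 5.74e-09), with the transferrin receptor Tfrc (7.40-fold, -2.89 ± 0.12) the largest fall, and the cell cycle list had 3 higher, 26 lower and 7 not called of 36 (3 and 26 adjusted over the list alone, median -0.82, adjusted p = 1.19e-05), with Ccne1 (4.38-fold, -2.13 ± 0.12), a cyclin of the entry into S phase, the largest. Glycolysis genes had 1 higher, 12 lower and 5 not called of 18 (1 and 12 adjusted over the list alone, median -0.46, adjusted p = 0.00296), led by the glucose transporter Slc2a3 (18.6-fold, -4.22 ± 0.11). Oxidative phosphorylation had 1 higher, 9 lower and 25 not called of 35 (0 and 8 adjusted over the list alone, median -0.15, adjusted p = 0.172). Chromatin regulators had 5 higher, 29 lower and 6 not called of 40 (5 and 29 adjusted over the list alone, median -0.89, adjusted p = 9.95e-07), with the DNA methyltransferase Dnmt3b (57.5-fold, -5.84 ± 0.14). Germ line genes had 1 higher, 11 lower and 4 not called of 16 (1 and 11 adjusted over the list alone, median -1.06, adjusted p = 0.000253). Interferon and antigen presentation genes had 1 higher, 23 lower and 5 not called of 29 (1 and 24 adjusted over the list alone, median -0.87, adjusted p = 9.95e-07), with the interferon-induced Ifit3 (12.2-fold, -3.60 ± 0.16).
Each of the remaining lists had genes called in both directions between MEFs and ES cells. Primitive endoderm markers had 13 higher, 4 lower and 6 not called of 23 (13 and 4 adjusted over the list alone, median 0.37, adjusted p = 0.00605, adjusted p = 0.0543 with an estimated correlation). Trophectoderm markers had 3 higher, 11 lower and 5 not called of 19 (3 and 11 adjusted over the list alone, median -0.49, -0.30 with bounds, adjusted p = 0.061). mesoderm and streak markers had 7 higher, 4 lower and 10 not called of 21 (7 and 4 adjusted over the list alone, median 0.057, adjusted p = 0.267). Neural and epiblast markers had 5 higher, 6 lower and 5 not called of 16 (5 and 6 adjusted over the list alone, median -0.0088, adjusted p = 0.875). Senescence and p53 genes had 7 higher, 11 lower and 10 not called of 28 (7 and 11 adjusted over the list alone, median 0.044, mean 0.046, test direction down, adjusted p = 0.688). Endothelium markers had 2 higher, 7 lower and 6 not called of 15 (2 and 7 adjusted over the list alone, median -0.23, adjusted p = 0.0995). Sex-linked genes had 2 higher, 1 lower and 1 not called of 4 (2 and 1 adjusted over the list alone, median 0.26, mean -0.10, test direction up, adjusted p = 0.781).

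The comparison of the 4 Esrrb lines (n = 8 arrays) with MEFs (n = 4 arrays) asks how far these lines had left the fibroblast state. Dnmt3l (at least 157-fold), Dppa4 (at least 147-fold), Trh (at least 211-fold), Esrrb (at least 72.5-fold), Pou5f1 (121-fold, 6.92 ± 0.098, above background on 1 of 4 MEF arrays) and Nanog (73.7-fold, 6.20 ± 0.087) were higher in the lines. Cdh1 (at least 15.2-fold) was higher as well. Igfbp5 (90.1-fold, -6.49 ± 0.096), Ptn (59.8-fold, -5.90 ± 0.089), Dcn (15.4-fold, -3.94 ± 0.091) and Hoxc8 (8.70-fold, -3.12 ± 0.073) were lower. Among these genes the highest adjusted p was 9.01e-14, and 10801 of 15642 genes were called, 5389 higher and 5412 lower, 3325 of them by at least 2-fold. With lines as replicates limma called 6951.
The pluripotency list in the Esrrb lines had 39 higher, 1 lower and 1 not called of 41 (39 and 1 adjusted over the list alone, median 4.39, 4.07 with bounds, adjusted p = 6.36e-21) against MEFs, and the epithelial junction list 17 higher, 0 lower and 1 not called of 18 (17 and 0 adjusted over the list alone, median 2.24, 1.76 with bounds, adjusted p = 5.47e-09). The fibroblast and matrix list had 1 higher, 46 lower and 2 not called of 49 (1 and 46 adjusted over the list alone, median -1.78, adjusted p = 1.19e-16). Hox genes had 1 higher, 25 lower and 4 not called of 30 (1 and 25 adjusted over the list alone, median -1.102, -0.83 with bounds, adjusted p = 4.83e-08). the blood and macrophage list had 1 higher, 16 lower and 2 not called of 19 (1 and 16 adjusted over the list alone, median -1.70, -1.67 with bounds, adjusted p = 1.67e-06). Cell cycle genes had 30 higher, 2 lower and 4 not called of 36 (30 and 2 adjusted over the list alone, median 0.91, adjusted p = 9.92e-08). Myc targets and ribosome biogenesis had 32 higher, 3 lower and 1 not called of 36 (32 and 3 adjusted over the list alone, median 1.22, adjusted p = 8.33e-09), with the nucleolar gene Ncl (4.48-fold, 2.16 ± 0.080). The cell cycle inhibitor gene Cdkn2a (7.36-fold, 2.88 ± 0.095) was higher in the lines, and the p53 target Pmaip1 (4.13-fold, 2.05 ± 0.089) too, while their list of senescence and p53 genes went both ways, with 13 higher, 12 lower and 3 not called of 28 (13 and 12 adjusted over the list alone, median 0.10, mean -0.026, test direction up, adjusted p = 0.752).
The single OSCK line (n = 2 arrays) differed from MEFs (n = 4 arrays) in pluripotency and matrix genes as well. Trh (at least 542-fold), Dnmt3l (at least 287-fold), Esrrb (at least 179-fold), Pou5f1 (128.3-fold, 7.00 ± 0.14, above background on 1 of 4 MEF arrays) and Nanog (108-fold, 6.76 ± 0.12) were higher, and Igfbp5 (118-fold, -6.88 ± 0.14), Dcn (32.7-fold, -5.03 ± 0.13) and the matrix gene Mfap4 (29.2-fold, -4.87 ± 0.14) lower, with a largest adjusted p of 8.37e-13. Here 9624 of 15642 genes were called, 4657 higher and 4967 lower, 3653 of them by at least 2-fold, and 4812 with lines as replicates. The pluripotency list had 40 higher, 1 lower and 0 not called of 41 (40 and 1 adjusted over the list alone, median 4.69, 4.20 with bounds, adjusted p = 1.98e-25). The fibroblast and matrix list had 1 higher, 43 lower and 5 not called of 49 (1 and 43 adjusted over the list alone, median -1.79, adjusted p = 7.85e-15). The cell cycle list had 30 higher, 1 lower and 5 not called of 36 (31 and 1 adjusted over the list alone, median 1.04, adjusted p = 9.34e-09).
Of the factor genes, Esrrb and Klf4 read lowest of the 5 lines in OSCE 8. The brighter Esrrb probe read 11.82 on log2 in ES cells, 12.40 in OSCK, 9.84 ± 0.10 in OSCE 8, 11.31 ± 0.090 in OSCE 13, 11.78 ± 0.034 in OSE T8 and 11.44 ± 0.12 in OSE T9 (SD, n = 2 arrays). It was not above background on any MEF array. A second Esrrb probe, above background on 8 of 16 arrays, read between 4.89 (OSCE 13) and 5.05 (OSE T8) in all 8 groups, MEFs included. Klf4 read 9.26 ± 0.27 in ES cells, 9.30 ± 0.13 in OSCK and 7.47 ± 0.12 in OSCE 8. Pou5f1 read between 11.53 and 11.99 in the 5 lines and 11.49 in ES cells. Nanog read between 11.13 and 11.91 in the lines. Myc read 6.21 in ES cells and between 5.44 and 6.02 in the lines. A probe cannot tell a transgene from the gene of the cell. The probes of Sox2 disagree: the brighter probe read 8.10 in OSCK and 8.08 in ES cells, another 6.10 and 8.26.

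**Figure D1:**
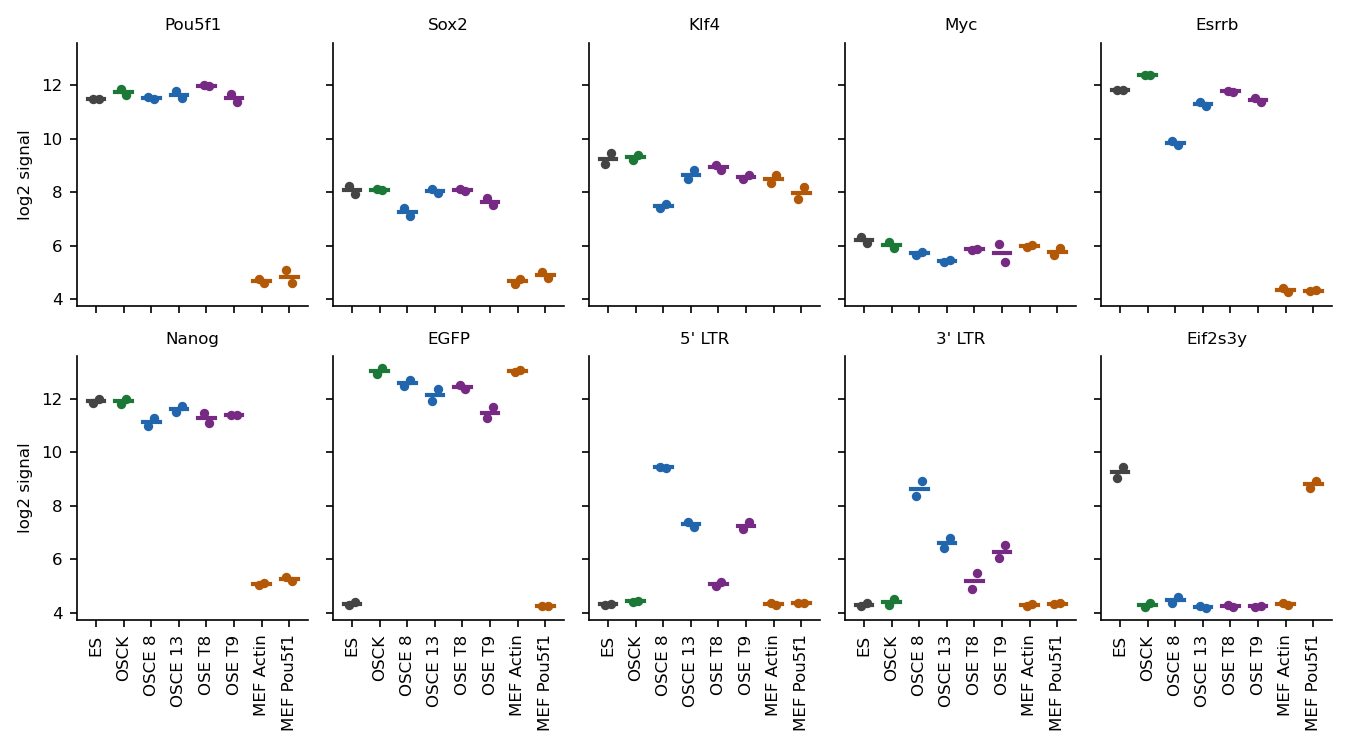
Levels of the factor genes and of the EGFP, viral long terminal repeat (LTR) and Eif2s3y probes on log2, 1 panel per probe and 1 point per array, with a bar at the mean of the 2 arrays of a group. Esrrb stands lowest of the lines in OSCE 8, at 9.84, and EGFP is on in the 5 iPS lines and the Actin-GFP MEFs.

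Probes for a transgene and for viral sequence, and those for Y-linked genes, were chosen after the values were seen. The probe for enhanced GFP (EGFP) read 13.05 ± 0.064 in Actin-GFP MEFs and between 11.49 and 13.05 in the 5 lines, and was at background in ES cells and Pou5f1-GFP MEFs. Probes for the LTRs of Moloney viruses, the backbone of common retroviral vectors, were at background in ES cells, MEFs and OSCK. The 5' LTR probe read 9.44 in OSCE 8, 7.31 in OSCE 13, 7.25 in OSE T9 and 5.07 in OSE T8, there above background on 1 of 2 arrays. Eif2s3y, a translation factor gene of the Y chromosome, read 9.25 in ES cells and 8.80 in Pou5f1-GFP MEFs, and was at background in Actin-GFP MEFs and all 5 lines. The probes of 2 other Y-linked genes did not follow it. Kdm5d read 6.54 in Pou5f1-GFP MEFs and 5.51 in Actin-GFP MEFs, and was at background in ES cells and the lines, except on 1 of 2 OSE T8 arrays. Uty read between 5.06 (OSE T8) and 5.32 (OSCE 8) in all 8 groups.

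Each array was placed on an axis from the ES mean (0) to the MEF mean (1) over 949 genes called between them with at least 4-fold. The positions were 0.103 ± 0.0024 for OSCE 13, 0.116 ± 0.0069 for OSCK, 0.125 ± 0.0020 for OSE T8, 0.183 ± 0.011 for OSE T9 and 0.202 ± 0.0012 for OSCE 8 (SD, n = 2 arrays). OSCE 8 and OSE T9 owe this to different axis sides. Over the 496 genes higher in ES cells they stood at 0.249 and 0.145, and over the 453 higher in MEFs at 0.135 and 0.238. Of the axis genes, 319 (OSCK) to 470 (OSCE 8) were called toward MEFs, and 59 (OSE T9) to 109 (OSE T8) away. In counts and positions a trait of the 1 ES line reads as toward MEFs, perhaps Eif2s3y and Ifit3. Across all genes the lines correlated with ES cells at r = 0.968 (OSCE 8) to 0.978 (OSCK), and with MEFs at 0.885 (OSE T8) to 0.906 (OSE T9). ES cells and MEFs correlated at 0.888.

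**Figure D2:**
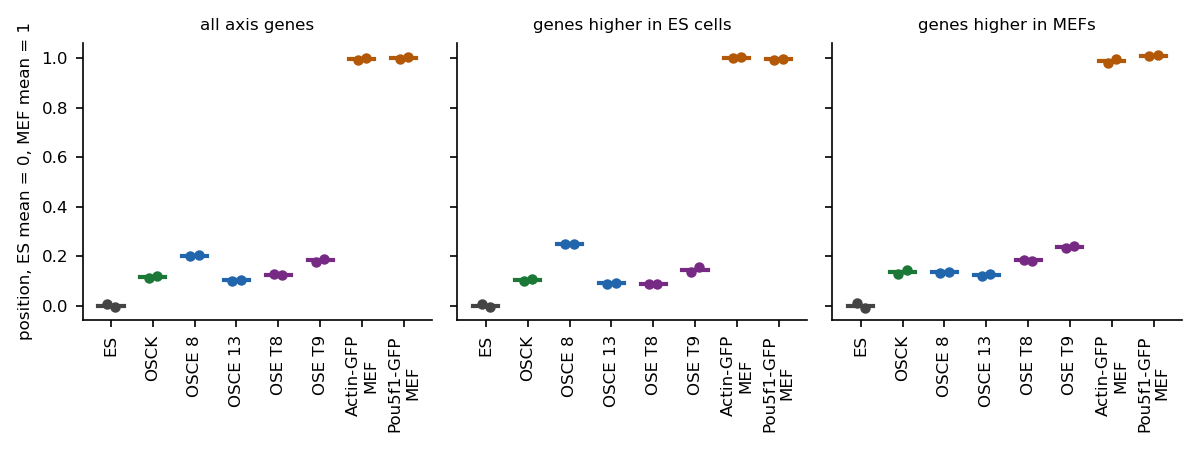
Position of each array on the axis from ES cells (0) to MEFs (1), without units, over all axis genes, over those higher in ES cells and over those higher in MEFs. Points are arrays and bars are means of the 2 arrays of a group; OSCE 8 stands at 0.202 over all axis genes and OSE T9 at 0.183.

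The comparison of the Esrrb lines (n = 8 arrays) with ES cells (n = 2 arrays) asks where lines made with Esrrb still differ from ES cells. Several of the largest falls were in genes that interferon induces. The ubiquitin-like modifier protease Usp18 (39.3-fold, -5.29 ± 0.19, above background on 6 of 8 Esrrb line arrays), Ifit3 (38.7-fold, -5.27 ± 0.15, above background on 6 of 8 Esrrb line arrays), the chemokine Ccl5 (36.0-fold, -5.17 ± 0.10, above background on 2 of 8 Esrrb line arrays), the antiviral synthetase Oas1g (20.0-fold, -4.32 ± 0.089) and the GTPase Gbp3 (14.2-fold, -3.83 ± 0.11) were lower. The Y-linked translation factor Eif2s3y (at least 19.4-fold) was lower too. Markers of the primitive streak, the site where mesoderm forms, were higher: T (at least 10.6-fold), also called Brachyury, and Gsc (4.60-fold, 2.20 ± 0.14, above background on 1 of 2 ES arrays). T read 11.75 in OSCE 8, 8.48 in OSE T8, 7.12 in OSCE 13 and 6.06 in OSE T9, against 4.71 in ES cells, so OSCE 8 carries much of its rise. The germ cell gene Dppa3 (8.68-fold, 3.12 ± 0.12) and the imprinted gene Peg3 (4.45-fold, 2.15 ± 0.10) rose, and the orphan nuclear receptor Nr5a2 (4.90-fold, -2.29 ± 0.092) fell. Among genes above background on both ES arrays, the largest rises were in Ipp (18.7-fold, 4.22 ± 0.14), an actin-binding protein, and Haus1 (13.9-fold, 3.80 ± 0.18), a spindle protein. For these genes the adjusted p was at most 2.25e-08.
Across lists, interferon and antigen presentation had 0 higher, 25 lower and 4 not called of 29 (1 and 26 adjusted over the list alone, median -1.20, adjusted p = 2.61e-27). mesoderm and streak had 14 higher, 2 lower and 5 not called of 21 (15 and 2 adjusted over the list alone, median 0.66, 0.44 with bounds, adjusted p = 4.43e-10), with medians by line from 1.36 (OSCE 8) to 0.11 (OSE T9). Pluripotency genes had 3 higher, 21 lower and 17 not called of 41 (4 and 24 adjusted over the list alone, median -0.45, adjusted p = 2.75e-07). By line the pluripotency medians were -0.86 in OSCE 8, -0.38 in OSE T9, -0.20 in OSCE 13 and -0.066 in OSE T8. The list was called only in OSCE 8 and OSE T9 (adjusted p = 0.052 there with an estimated correlation). the reprogramming factors had 0 higher, 4 lower and 2 not called of 6 (0 and 5 adjusted over the list alone, median -0.55, adjusted p = 0.00484), with Esrrb (1.65-fold, -0.73 ± 0.086) and Klf4 (1.81-fold, -0.86 ± 0.14), both lowest in OSCE 8. Epithelial junction genes had 8 higher, 0 lower and 10 not called of 18 (11 and 0 adjusted over the list alone, median 0.34, 0.31 with bounds, adjusted p = 0.000432), led by the keratin Krt18 (2.59-fold, 1.37 ± 0.099). Krt18 read 9.09 (OSCE 8), 8.74 (OSCE 13), 6.71 (OSE T8) and 5.60 (OSE T9) against 6.16 in ES cells. Its rise thus rests mostly on the OSCE lines, and the list had no gene higher in OSE T9. Imprinted genes had 11 higher, 2 lower and 17 not called of 30 (13 and 3 adjusted over the list alone, median 0.24, 0.23 with bounds, adjusted p = 0.000432). Cell cycle genes had 7 higher, 1 lower and 28 not called of 36 (7 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.00484), with the mitotic kinase Plk1 (2.13-fold, 1.09 ± 0.087). Glycolysis genes had 0 higher, 7 lower and 11 not called of 18 (1 and 8 adjusted over the list alone, median -0.21, adjusted p = 0.00209), with Slc2a3 (1.83-fold, -0.87 ± 0.10). By line the list was called in OSE T9 and OSE T8 (adjusted p = 0.0823 there with an estimated correlation), but in neither OSCE line. Primitive endoderm markers had 9 higher, 2 lower and 12 not called of 23 (9 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.00553, adjusted p = 0.0704 with an estimated correlation), with the lipid carrier Apoe (2.11-fold, 1.08 ± 0.095). The fibroblast and matrix list, whose genes feeder cells express, had 13 higher, 8 lower and 28 not called of 49 (15 and 10 adjusted over the list alone, median 0.090, adjusted p = 0.249). the blood and macrophage list had 5 higher, 2 lower and 12 not called of 19 (6 and 2 adjusted over the list alone, median 0.24, 0.15 with bounds, adjusted p = 0.0667). The latter was called without OSCE 8 replicate 1, at adjusted p = 0.0374 (0.0374 to 0.269 over all alternatives).
In all, 3521 of 15642 genes were called, 1757 higher and 1764 lower, 493 of them by at least 2-fold. With lines as replicates limma called 97 genes, 33 of them higher. The count was 2133 without ES replicate 1 and 2133 without ES replicate 2.
The single OSCK line (n = 2 arrays), made without Esrrb by its name, showed the interferon change against ES cells (n = 2 arrays) as well, with Usp18 (51.2-fold, -5.68 ± 0.23), Ifit3 (at least 41.1-fold) and Oas1g (36.9-fold, -5.21 ± 0.11) lower. Ipp (25.7-fold, 4.68 ± 0.18) and Dppa3 (9.63-fold, 3.27 ± 0.15) were higher, as were T (at least 3.94-fold) and Esrrb (1.495-fold, 0.58 ± 0.11) itself. The chromatin remodelling gene Smarcc1 (5.49-fold, -2.46 ± 0.17) was lower. No gene named here had an adjusted p above 0.00155. Interferon and antigen presentation had 0 higher, 27 lower and 2 not called of 29 (0 and 28 adjusted over the list alone, median -1.64, -1.53 with bounds, adjusted p = 2.12e-33). Genes of mesoderm and streak had 8 higher, 0 lower and 13 not called of 21 (9 and 0 adjusted over the list alone, median 0.24, adjusted p = 0.000149). Cell cycle genes had 12 higher, 0 lower and 24 not called of 36 (12 and 1 adjusted over the list alone, median 0.28, adjusted p = 2.39e-05). Glycolysis genes had 5 higher, 0 lower and 13 not called of 18 (8 and 0 adjusted over the list alone, median 0.19, adjusted p = 0.0113, adjusted p = 0.0928 with an estimated correlation). Imprinted genes had 10 higher, 2 lower and 18 not called of 30 (11 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.00431). Pluripotency genes had 5 higher, 6 lower and 30 not called of 41 (5 and 6 adjusted over the list alone, median 0.025, adjusted p = 0.993). Blood and macrophage markers had 6 higher, 1 lower and 12 not called of 19 (7 and 1 adjusted over the list alone, median 0.23, 0.13 with bounds, adjusted p = 0.00318, adjusted p = 0.133 with an estimated correlation), with Lyz2 (3.25-fold, 1.70 ± 0.16). fibroblast markers had 11 higher, 7 lower and 31 not called of 49 (14 and 8 adjusted over the list alone, median 0.20, adjusted p = 0.072). The fibroblast list was called without ES replicate 1, at adjusted p = 0.0203, and without OSCK replicate 1, at 0.0451 (0.00503 to 0.573 over all alternatives). In OSCK, 2647 of 15642 genes were called, 1271 higher and 1376 lower, 562 of them by at least 2-fold. The count was 1740 without OSCK replicate 2.
The 5 lines share changes against ES cells: 290 genes were called higher and 418 lower in every line. Simulated lines without change, which share simulated ES arrays, gave none. That simulation holds only noise between arrays and no trait of the single ES line. It thus cannot tell such a trait from changes of the lines. The shared genes include 16 of 29 interferon and antigen presentation genes (lower) and the streak genes T, Gsc and Msx1 (higher). Dppa3, Mest and Peg3, the cell cycle genes Plk1 and Cdc6, and Cdkn2a and Pmaip1 were higher in all 5, and Nr5a2, Smarcc1 and the inflammatory genes Il6 and Cxcl1 lower. Of the fibroblast and matrix list, Ccn2, Twist2 and Cd44 were lower in all 5 and Pdgfra higher. Because the ES arrays enter every comparison, changes of 2 lines correlate across genes without any shared biology. The correlations were 0.620 to 0.745, and 0.485 to 0.506 in the simulation.

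**Figure D3:**
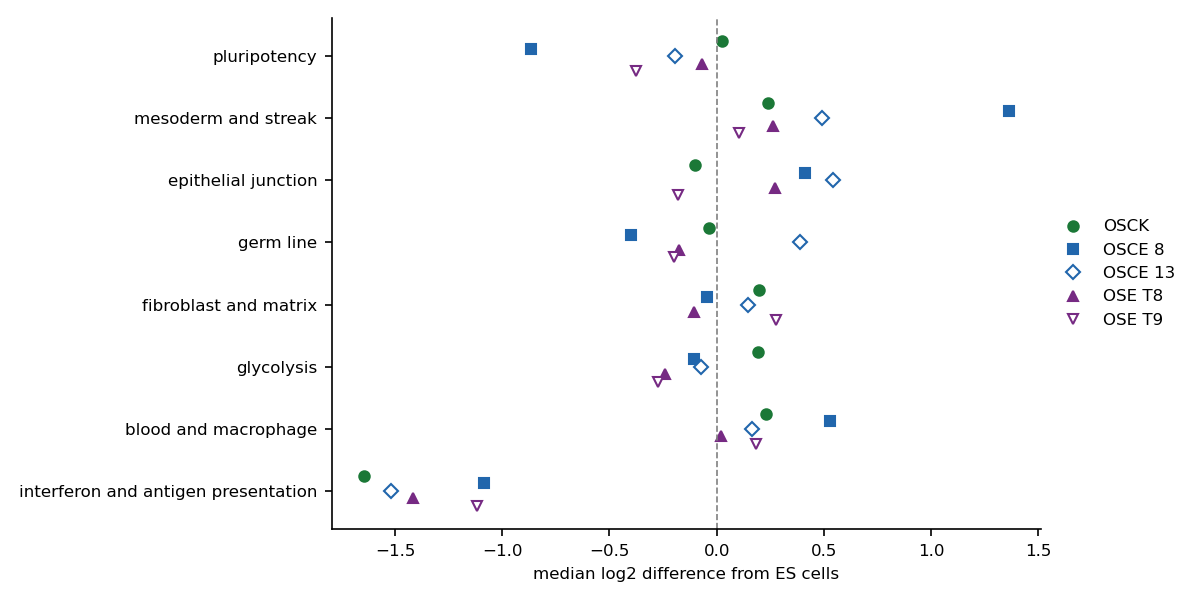
Median log2 difference from ES cells of 8 fixed gene lists, 1 point per iPS line; the dashed line marks no difference. Interferon and antigen presentation genes are lower in every line, at -1.20 for the mean of the Esrrb lines, and mesoderm and streak genes are highest in OSCE 8, at 1.36.

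Line by line, OSCE 8 (n = 2 arrays) had the most genes called against ES cells (n = 2 arrays) of the 5 lines, early mesoderm genes among them. T (at least 112-fold), the transcription factors Lhx1 (at least 12.9-fold), Gsc (14.3-fold, 3.83 ± 0.17, above background on 1 of 2 ES arrays) and Eomes (8.56-fold, 3.10 ± 0.16) and the growth factors Fgf8 (at least 11.7-fold) and Fgf5 (12.9-fold, 3.69 ± 0.16) were higher. The keratin Krt8 (11.6-fold, 3.53 ± 0.17) and the endoderm factor Gata6 (4.25-fold, 2.09 ± 0.14) were higher, and Esrrb (3.95-fold, -1.98 ± 0.11), Klf4 (3.45-fold, -1.79 ± 0.18) and Nr5a2 (10.1-fold, -3.34 ± 0.12) lower. The largest adjusted p of these genes was 3.2e-06. Streak and mesoderm genes had 15 higher, 1 lower and 5 not called of 21 (16 and 2 adjusted over the list alone, median 1.36, 1.16 with bounds, adjusted p = 1.49e-14). Pluripotency genes had 3 higher, 28 lower and 10 not called of 41 (4 and 28 adjusted over the list alone, median -0.86, adjusted p = 3.77e-13). The reprogramming factors had 0 higher, 4 lower and 2 not called of 6 (0 and 5 adjusted over the list alone, median -0.81, adjusted p = 0.000393). Germ line genes had 1 higher, 7 lower and 8 not called of 16 (1 and 7 adjusted over the list alone, median -0.40, -0.38 with bounds, adjusted p = 0.00124). Genes of interferon and antigen presentation had 2 higher, 21 lower and 6 not called of 29 (2 and 21 adjusted over the list alone, median -1.08, adjusted p = 2.39e-15). Blood and macrophage markers had 11 higher, 2 lower and 6 not called of 19 (12 and 2 adjusted over the list alone, median 0.53, 0.34 with bounds, adjusted p = 0.000484, adjusted p = 0.0594 with an estimated correlation), with Lyz2 (9.02-fold, 3.17 ± 0.16). Fibroblast and matrix genes had 3 higher, 10 lower and 36 not called of 49 (3 and 10 adjusted over the list alone, median -0.043, adjusted p = 0.19). Glycolysis genes had 1 higher, 6 lower and 11 not called of 18 (3 and 7 adjusted over the list alone, median -0.11, adjusted p = 0.167). In OSCE 8, 3778 of 15642 genes were called, 1815 higher and 1963 lower, 897 of them by at least 2-fold.
OSCE 13 (n = 2 arrays) differed from ES cells (n = 2 arrays) in germ line and X-linked genes. The homeobox genes Rhox9 (16.3-fold, 4.02 ± 0.14) and Rhox6 (11.2-fold, 3.49 ± 0.20, above background on 1 of 2 ES arrays), the testis protease Usp26 (16.9-fold, 4.08 ± 0.15), Dppa3 (15.0-fold, 3.90 ± 0.15) and the germ cell kinase Stk31 (3.67-fold, 1.87 ± 0.14) were higher, as were Krt18 (5.99-fold, 2.58 ± 0.13) and the adhesion gene Fermt1 (15.4-fold, 3.95 ± 0.13, above background on 1 of 2 ES arrays). Among these genes the highest adjusted p was 3.07e-07. Trophectoderm markers had 9 higher, 0 lower and 10 not called of 19 (11 and 0 adjusted over the list alone, median 0.39, adjusted p = 9.65e-09). Epithelial junction genes had 12 higher, 0 lower and 6 not called of 18 (12 and 0 adjusted over the list alone, median 0.54, adjusted p = 9.41e-09). Germ line genes had 7 higher, 1 lower and 8 not called of 16 (7 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.000106). Mesoderm and streak had 12 higher, 0 lower and 9 not called of 21 (13 and 2 adjusted over the list alone, median 0.49, adjusted p = 4.35e-08). Glycolysis genes had 1 higher, 4 lower and 13 not called of 18 (1 and 4 adjusted over the list alone, median -0.075, adjusted p = 0.311). Interferon and antigen presentation had 1 higher, 25 lower and 3 not called of 29 (1 and 26 adjusted over the list alone, median -1.52, -1.48 with bounds, adjusted p = 1.03e-24). pluripotency had 4 higher, 10 lower and 27 not called of 41 (4 and 11 adjusted over the list alone, median -0.20, adjusted p = 0.0598). Without ES replicate 1 the pluripotency list was called lower, at adjusted p = 0.0126 (0.00371 to 0.348 over all alternatives). In OSCE 13, 3038 of 15642 genes were called, 1528 higher and 1510 lower, 650 of them by at least 2-fold. The 440 X-linked genes had a median difference of 0.41, with 84.5% above 0 (adjusted p = 2.5e-23 over 20 chromosomes).
OSE T8 (n = 2 arrays) differed from ES cells (n = 2 arrays) in matrix genes of both directions. The adipocyte gene Medag (18.6-fold, 4.22 ± 0.13, above background on 1 of 2 ES arrays), the proteoglycans Lum (14.3-fold, 3.84 ± 0.18, above background on 1 of 2 ES arrays) and Dcn (7.46-fold, 2.90 ± 0.15) and Igfbp5 (4.85-fold, 2.28 ± 0.16) were higher, and the matricellular gene Ccn2 (3.60-fold, -1.85 ± 0.16) lower. T (at least 11.6-fold), Gsc (7.21-fold, 2.85 ± 0.17, above background on 1 of 2 ES arrays) and H19 (3.91-fold, 1.97 ± 0.19) were higher. For these genes the adjusted p was at most 3.03e-06. Genes of fibroblasts and matrix had 9 higher, 15 lower and 25 not called of 49 (10 and 15 adjusted over the list alone, median -0.10, adjusted p = 0.203). Imprinted genes had 12 higher, 2 lower and 16 not called of 30 (14 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.000142). Genes of mesoderm and streak had 9 higher, 2 lower and 10 not called of 21 (9 and 2 adjusted over the list alone, median 0.26, 0.19 with bounds, adjusted p = 0.000142). Cell cycle genes had 6 higher, 0 lower and 30 not called of 36 (7 and 2 adjusted over the list alone, median 0.23, adjusted p = 0.00137). Genes of interferon and antigen presentation had 0 higher, 24 lower and 5 not called of 29 (0 and 25 adjusted over the list alone, median -1.42, adjusted p = 1.77e-27). Pluripotency genes had 6 higher, 6 lower and 29 not called of 41 (6 and 6 adjusted over the list alone, median -0.066, adjusted p = 0.763). Glycolysis genes had 1 higher, 8 lower and 9 not called of 18 (1 and 8 adjusted over the list alone, median -0.24, adjusted p = 0.0104, adjusted p = 0.0823 with an estimated correlation). In OSE T8, 3237 of 15642 genes were called, 1626 higher and 1611 lower, 756 of them by at least 2-fold.
OSE T9 (n = 2 arrays) had higher levels of fibroblast genes than ES cells (n = 2 arrays). Medag (22.2-fold, 4.47 ± 0.13, above background on 1 of 2 ES arrays), Lum (12.1-fold, 3.59 ± 0.18, above background on 1 of 2 ES arrays), the collagen gene Col3a1 (3.69-fold, 1.89 ± 0.31) and Dcn (3.01-fold, 1.59 ± 0.15) were higher. Dnmt3l (3.18-fold, -1.67 ± 0.15), the Nodal antagonist Lefty1 (2.90-fold, -1.54 ± 0.15) and Krt8 (2.70-fold, -1.44 ± 0.17) were lower, and so were the glycolytic enzyme Pfkl (3.09-fold, -1.63 ± 0.16) and the glucose transporter Slc2a1 (2.64-fold, -1.40 ± 0.17). No gene named here had an adjusted p above 0.000533. Fibroblast and matrix had 20 higher, 4 lower and 25 not called of 49 (20 and 4 adjusted over the list alone, median 0.28, adjusted p = 3.2e-05, adjusted p = 0.0977 with an estimated correlation). Glycolysis genes had 0 higher, 7 lower and 11 not called of 18 (0 and 8 adjusted over the list alone, median -0.27, adjusted p = 3.31e-05). Mesoderm and streak had 7 higher, 2 lower and 12 not called of 21 (7 and 2 adjusted over the list alone, median 0.11, 0.056 with bounds, adjusted p = 0.164). Epithelial junction genes had 0 higher, 5 lower and 13 not called of 18 (0 and 5 adjusted over the list alone, median -0.18, -0.093 with bounds, adjusted p = 0.0925), and were called lower without ES replicate 1, at adjusted p = 0.0214 (0.0214 to 0.288 over all alternatives). Pluripotency genes had 2 higher, 17 lower and 22 not called of 41 (2 and 21 adjusted over the list alone, median -0.38, adjusted p = 5.02e-07, adjusted p = 0.052 with an estimated correlation). Imprinted genes had 10 higher, 1 lower and 19 not called of 30 (12 and 1 adjusted over the list alone, median 0.18, 0.14 with bounds, adjusted p = 0.00193). Genes of interferon and antigen presentation had 0 higher, 23 lower and 6 not called of 29 (0 and 26 adjusted over the list alone, median -1.12, adjusted p = 8.13e-25). In OSE T9, 3176 of 15642 genes were called, 1673 higher and 1503 lower, 668 of them by at least 2-fold, or 2027 called without ES replicate 2. The 647 genes of chromosome 8 had a median difference of 0.19 (adjusted p = 1.1e-06).

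Comparisons among iPS lines ask whether lines with other factor sets differ. The OSCE lines (n = 4 arrays) against OSCK (n = 2 arrays) had higher Krt8 (9.48-fold, 3.25 ± 0.14), Krt18 (6.43-fold, 2.68 ± 0.11), Fgf8 (at least 6.08-fold), T (5.70-fold, 2.51 ± 0.12) and the muscle actin Acta1 (4.52-fold, 2.18 ± 0.15). Esrrb (3.54-fold, -1.83 ± 0.094), Klf4 (2.36-fold, -1.24 ± 0.16) and the Akt cofactor Tcl1 (2.93-fold, -1.55 ± 0.12) were lower, and so were the glycolytic enzyme Pfkp (2.35-fold, -1.23 ± 0.12) and the kinase Pdk1 (2.20-fold, -1.14 ± 0.12), which keeps pyruvate from the mitochondria. The largest adjusted p of these genes was 5.82e-05. Streak and mesoderm genes had 13 higher, 1 lower and 7 not called of 21 (13 and 1 adjusted over the list alone, median 0.76, 0.70 with bounds, adjusted p = 7.72e-13). Epithelial junction genes had 10 higher, 1 lower and 7 not called of 18 (10 and 1 adjusted over the list alone, median 0.52, adjusted p = 9.9e-10). Pluripotency genes had 2 higher, 24 lower and 15 not called of 41 (3 and 26 adjusted over the list alone, median -0.52, adjusted p = 7.72e-13). Glycolysis genes had 0 higher, 6 lower and 12 not called of 18 (0 and 8 adjusted over the list alone, median -0.25, adjusted p = 1.58e-06). Here 2192 of 15642 genes were called, 1132 higher and 1060 lower, 311 of them by at least 2-fold, or 1178 without OSCK replicate 1 and 1251 without OSCK replicate 2. With lines as replicates limma called 0 genes, with 775 at an unadjusted p under 0.05. T read 11.75 in OSCE 8 and 7.12 in OSCE 13, against 6.93 in OSCK, so its rise rests on OSCE 8. A single line stands for OSCK, so line and factor set cannot be told apart.
The OSE lines (n = 4 arrays) against OSCK (n = 2 arrays) had lower glycolysis genes, 0 higher, 13 lower and 5 not called of 18 (0 and 14 adjusted over the list alone, median -0.58, adjusted p = 1.23e-11), with Pfkl (2.62-fold, -1.39 ± 0.14), Pfkp (2.59-fold, -1.37 ± 0.12), the triose isomerase Tpi1 (2.08-fold, -1.06 ± 0.086) and Slc2a3 (2.10-fold, -1.07 ± 0.11). The lysine-degrading enzyme Aass (13.8-fold, 3.79 ± 0.096), Medag (7.10-fold, 2.83 ± 0.11) and Dcn (6.37-fold, 2.67 ± 0.13) were higher, and the thymic regulator Aire (6.69-fold, -2.74 ± 0.11) lower. Among these genes the highest adjusted p was 1.23e-05. In OSCK itself 5 genes of this list were higher than in ES cells and 0 lower (median 0.19, adjusted p = 0.0113, 0.0928 with an estimated correlation), so this difference is not one of the OSE lines alone. Pluripotency genes had 3 higher, 11 lower and 27 not called of 41 (4 and 14 adjusted over the list alone, median -0.18, adjusted p = 0.000618, adjusted p = 0.149 with an estimated correlation). Blood and macrophage markers had 0 higher, 8 lower and 11 not called of 19 (0 and 8 adjusted over the list alone, median -0.30, -0.21 with bounds, adjusted p = 0.000141, adjusted p = 0.0865 with an estimated correlation). In this comparison 2228 of 15642 genes were called, 1228 higher and 1000 lower, 257 of them by at least 2-fold, or 1161 without OSCK replicate 1 and 1112 without OSCK replicate 2. With lines as replicates limma called 0 genes, with 841 at an unadjusted p under 0.05.
The OSE lines (n = 4 arrays) against the OSCE lines (n = 4 arrays) had lower streak genes, Fgf8 (4.91-fold, -2.30 ± 0.10, above background on 2 of 4 OSE arrays), T (4.49-fold, -2.17 ± 0.098), Evx1 (3.78-fold, -1.92 ± 0.084) and Eomes (3.32-fold, -1.73 ± 0.11), and lower keratins, Krt8 (11.1-fold, -3.48 ± 0.12) and Krt18 (6.78-fold, -2.76 ± 0.089). Lum (13.7-fold, 3.77 ± 0.13, above background on 1 of 4 OSCE arrays), Medag (11.04-fold, 3.46 ± 0.094) and Dcn (8.97-fold, 3.16 ± 0.11) were higher, and so were Esrrb (2.05-fold, 1.04 ± 0.077) and the pluripotency marker Zfp42 (2.04-fold, 1.03 ± 0.12). For these genes the adjusted p was at most 2.23e-05. The sets overlap in T, at 11.75 (OSCE 8), 7.12 (OSCE 13), 8.48 (OSE T8) and 6.06 (OSE T9). They overlap in Esrrb too, at 9.84, 11.31, 11.78 and 11.44 in that order. Both differences rest on OSCE 8, as does most of that of Evx1, at 8.63 in OSCE 8 and 5.81 in OSCE 13 against 5.51 in OSE T8. Mesoderm and streak had 1 higher, 16 lower and 4 not called of 21 (1 and 18 adjusted over the list alone, median -0.74, adjusted p = 2.84e-14). By line against ES cells its medians were 1.36 (OSCE 8), 0.49 (OSCE 13), 0.26 (OSE T8) and 0.11 (OSE T9). OSCE 8 carries much of this too. Trophectoderm markers had 2 higher, 15 lower and 2 not called of 19 (3 and 15 adjusted over the list alone, median -0.64, -0.57 with bounds, adjusted p = 3.16e-09). Epithelial junction genes had 2 higher, 12 lower and 4 not called of 18 (2 and 13 adjusted over the list alone, median -0.46, -0.40 with bounds, adjusted p = 9.79e-08). Krt8 and Krt18 count in both of these lists. Pluripotency genes had 22 higher, 6 lower and 13 not called of 41 (25 and 7 adjusted over the list alone, median 0.35, adjusted p = 4.19e-05, adjusted p = 0.0946 with an estimated correlation). Genes of fibroblasts and matrix had 16 higher, 13 lower and 20 not called of 49 (18 and 16 adjusted over the list alone, median 0.082, adjusted p = 0.501). Between these sets 3642 of 15642 genes were called, 1908 higher and 1734 lower, 279 of them by at least 2-fold. With lines as replicates limma called 3 genes, Medag, Lum and Cxcl15 (the last named after the values were seen), with 1411 at an unadjusted p under 0.05.
Lines of 1 factor set differed from each other as well. OSCE 8 against OSCE 13 (n = 2 arrays each, on other slides) had higher T (24.9-fold, 4.64 ± 0.14), Lhx1 (8.61-fold, 3.11 ± 0.14) and the streak factor Mixl1 (at least 6.62-fold), and lower Fmr1nb (at least 51.4-fold), a testis antigen, Rhox9 (53.1-fold, -5.73 ± 0.14), Rhox5 (12.6-fold, -3.66 ± 0.13) and Stk31 (5.58-fold, -2.48 ± 0.14). No gene named here had an adjusted p above 2.35e-08. Genes of mesoderm and streak had 14 higher, 3 lower and 4 not called of 21 (14 and 5 adjusted over the list alone, median 1.16, 1.096 with bounds, adjusted p = 1.67e-09). Pluripotency genes had 2 higher, 28 lower and 11 not called of 41 (2 and 29 adjusted over the list alone, median -0.80, -0.78 with bounds, adjusted p = 8.89e-16). Germ line genes had 0 higher, 11 lower and 5 not called of 16 (0 and 11 adjusted over the list alone, median -1.20, -1.02 with bounds, adjusted p = 3.58e-12). Here 2881 of 15642 genes were called, 1354 higher and 1527 lower, 562 of them by at least 2-fold, or 1884 without OSCE 8 replicate 1, 1829 without OSCE 8 replicate 2, 1866 without OSCE 13 replicate 1 and 1851 without OSCE 13 replicate 2. OSE T8 against OSE T9 (n = 2 arrays each, on the same slides) had higher securin, Pttg1 (9.62-fold, 3.27 ± 0.20), higher T (5.37-fold, 2.42 ± 0.14), Gsc (4.63-fold, 2.21 ± 0.17) and Lefty1 (3.32-fold, 1.73 ± 0.15), and lower Cald1 (3.99-fold, -2.00 ± 0.25), an actin regulator, Thbs1 (3.38-fold, -1.76 ± 0.15), a matrix protein, and Lyz2 (4.17-fold, -2.06 ± 0.16). The largest adjusted p of these genes was 9.71e-05. Fibroblast and matrix had 2 higher, 22 lower and 25 not called of 49 (2 and 25 adjusted over the list alone, median -0.46, adjusted p = 1.1e-11). pluripotency had 13 higher, 0 lower and 28 not called of 41 (21 and 1 adjusted over the list alone, median 0.35, adjusted p = 1.83e-07). Of 15642 genes, 1953 were called, 845 of them higher in OSE T8, or 957 without OSE T8 replicate 2 and 1189 without OSE T9 replicate 2. A fit of these 2 groups alone called 499.

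Actin-GFP MEFs (n = 2 arrays) differed from Pou5f1-GFP MEFs (n = 2 arrays) in immune genes. The protease inhibitor Serpina3n (14.2-fold, 3.83 ± 0.15), the antibody receptor Fcgr3 (8.12-fold, 3.02 ± 0.17), Lyz2 (5.62-fold, 2.49 ± 0.16), the endotoxin receptor Cd14 (5.44-fold, 2.44 ± 0.13) and the proteasome gene Psmb9 (3.88-fold, 1.96 ± 0.15, above background on 1 of 2 Pou5f1-GFP MEF arrays) were higher. The antibody receptor chain Fcer1g (at least 12.3-fold) was lower, the one gene of the blood and macrophage list called so. Eif2s3y (at least 14.7-fold), the retinol-oxidising enzyme Adh7 (at least 18.2-fold), the imprinted RNA Rian (at least 7.17-fold), the embryonic myosin Myh3 (4.44-fold, -2.15 ± 0.23) and the distal limb gene Hoxd12 (3.70-fold, -1.89 ± 0.10) were lower. Among these genes the highest adjusted p was 1.62e-05. Blood and macrophage markers had 13 higher, 1 lower and 5 not called of 19 (13 and 1 adjusted over the list alone, median 1.43, adjusted p = 2.23e-15). Interferon and antigen presentation had 15 higher, 0 lower and 14 not called of 29 (17 and 0 adjusted over the list alone, median 0.43, adjusted p = 2.32e-14). Muscle genes had 0 higher, 10 lower and 6 not called of 16 (0 and 10 adjusted over the list alone, median -0.89, -0.58 with bounds, adjusted p = 1.24e-08). Imprinted genes had 0 higher, 7 lower and 23 not called of 30 (1 and 9 adjusted over the list alone, median -0.19, -0.17 with bounds, adjusted p = 0.000307). Genes of fibroblasts and matrix had 2 higher, 6 lower and 41 not called of 49 (2 and 6 adjusted over the list alone, median 0.012, mean -0.032, test direction down, adjusted p = 0.948). Between the MEF types 1795 of 15642 genes were called, 832 higher and 963 lower, 460 of them by at least 2-fold, or 1129 without Pou5f1-GFP MEF replicate 1 and 1140 without Actin-GFP MEF replicate 1.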

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

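Every test of an explanation in this part, and the test by chromosome itself, was chosen only after the result was seen; the comparisons of lines by list were planned.
Lines made with the same named factors differed from each other, by the test of the difference itself. Between OSCE 8 and OSCE 13 (n = 2 arrays each), the list medians on log2 were 1.16 (adjusted p = 1.67e-09, 0.00223 with an estimated correlation) for mesoderm and streak, -0.80 (adjusted p = 8.89e-16, 0.00585 with an estimated correlation) for pluripotency and -1.20 (adjusted p = 3.58e-12, 0.00223 with an estimated correlation) for germ line genes. The reprogramming factors had -0.64 (adjusted p = 0.00309, 0.0468 with an estimated correlation) and endothelium -0.41 (adjusted p = 0.00309, 0.0432 with an estimated correlation). These lines were hybridised on different slides, so line and slide cannot be told apart here. Over all alternatives the adjusted p of these 5 lists lay between 1.7e-30 and 0.0468. The lists were chosen for an adjusted p under 0.05 at both the preset and the estimated correlation. The highest value is that with the estimated correlation, so the choice itself kept it under 0.05.
Between OSE T8 and OSE T9 (n = 2 arrays each), which share their slides, the medians were -0.46 (adjusted p = 1.1e-11, 0.025 with an estimated correlation) for fibroblast and matrix, 0.35 (adjusted p = 1.83e-07, 0.0442 with an estimated correlation) for pluripotency and 0.34 (adjusted p = 5.35e-06, 0.0392 with an estimated correlation) for epithelial junction genes. Mesoderm and streak had 0.25 (adjusted p = 7.6e-05, 0.025 with an estimated correlation), neural and epiblast 0.23 (adjusted p = 0.00689, 0.0454 with an estimated correlation) and cell cycle 0.20 (adjusted p = 0.00914, 0.0495 with an estimated correlation). Over all alternatives the adjusted p of these 6 lists lay between 2.66e-17 and 0.0495. On each of the 2 shared slides alone the fibroblast and matrix median was -0.46 and -0.39, and that of pluripotency 0.30 and 0.42.
X-linked genes were lower in OSCE 8 than in OSCE 13, with a median of -0.28 (adjusted p = 7.92e-12, 0.00011 with an estimated correlation). Against ES cells the shift of these genes from all other genes was 0.42 in OSCE 13 (adjusted p = 2.5e-23, 7.85e-06 with an estimated correlation). Over all alternatives the shift lay between 0.11 (no filter on dim probes) and 0.48 and its adjusted p between 7.33e-25 and 7.85e-06. The slide is argued against, as the lowest shift from OSE T8 or OSE T9 on the slides they share with OSCE 13 was 0.39, and so is the normalization, as the lower shift without background correction or quantile normalization was 0.33. The 266 X-linked genes above background on all arrays shifted by 0.52, with 91.7% above the median of other genes, so a larger dose of X-linked genes in OSCE 13 may be the cause, as a hypothesis. Xist, the RNA that silences an X chromosome, was called higher in OSCE 13 than in ES cells (1.42-fold, adjusted p = 0.0198) and than in OSCE 8 (2.46-fold, adjusted p = 1.16e-05). It read 7.96 in OSCE 13, 7.70 in OSE T9, 7.45 in ES cells, 8.59 in Actin-GFP MEFs, 7.18 in OSCK, 7.08 in OSE T8 and 6.66 in OSCE 8, while X-linked genes of OSE T9 had a median of 0.040 against ES cells (adjusted p = 0.809). A second Xist probe was at background on all arrays. The labels give no sex or karyotype, so the number of X chromosomes was not tested.
Genes of chromosome 8 were lower in OSE T8 than in OSE T9, with a median of -0.19 (adjusted p = 1.84e-09, 0.016 with an estimated correlation). Against ES cells their shift in OSE T9 was 0.19 (adjusted p = 1.1e-06, 0.0471 with an estimated correlation). Over all alternatives the shift lay between 0.075 (no filter) and 0.23 and its adjusted p between 9.01e-08 and 0.0471. The lowest shift within a slide, from OSE T8 or OSCE 13, was 0.17, which argues against the slide. Fibroblast RNA is argued against too, because the 214 chromosome 8 genes that are lower in MEFs shifted by 0.35 against other such genes. The 467 genes above background on all arrays shifted by 0.24, with 78.6% above the median of other genes, so a larger dose of chromosome 8 in some or all cells of OSE T9 may be the cause, as a hypothesis.
Probes outside the comparisons gave a signal where ES cells had none. The highest mean of an iPS line on log2 was 13.05 for EGFP (OSCK), 9.44 for the 5' LTR and 8.64 for the 3' LTR (both OSCE 8). Actin-GFP MEFs read 13.05 for EGFP and Pou5f1-GFP MEFs were at background, as were both for the LTRs. No explanation of these signals was tested.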

How the results depend on the processing

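The alternatives were fixed before the data were examined, except the tests without the OSE T9 or OSCE 8 line, those of chromosome shifts and those of axis genes called toward MEFs, which were chosen only after the results were seen. The cause of a change was not tested except where its construction shows it.
The 181 named changes kept direction and call in 2896 results without 1 array and 1440 others, each for 1 gene in 1 fit. Their choice by call and size favours this, and it says nothing of other genes. The filter of at least 8 arrays removed 8 of the 181. Gene and list values could not be computed from the series matrix. Fits with lines as replicates or only the compared groups were run for counts alone and are left out. With lines as replicates no gene was called between OSCE or OSE and OSCK, so genes named there lose their call. Between OSE and OSCE, that fit called only Medag, Lum and Cxcl15. Of the 111 list tests given, none reversed; 5 of 1776 results without 1 array and 10 of 999 others became called and 14 were lost, 13 of these with an estimated correlation, where 92 in place of 142 of all list tests were called. In those 13 lists the adjusted p was 4.38e-11 to 0.0467 under the other alternatives. The other lost call was muscle in MEFs, with the filter of at least 8 arrays (adjusted p over the alternatives 0.000322 to 0.0563). Lists called under some alternatives alone were trophectoderm (0.0154 to 0.21) and endothelium (0.0427 to 0.135) in MEFs without the filter or with a slide block, pluripotency in OSCE 13 (0.0126 without ES replicate 1, range 0.00371 to 0.348), fibroblast genes in OSCK (0.0203 without ES replicate 1, 0.0451 without OSCK replicate 1, range 0.00503 to 0.573) and in OSE against OSCE with a slide block (0.0224 to 0.802), epithelial junction genes in OSE T9 (0.0214 without ES replicate 1, range 0.0214 to 0.288), and blood genes in the Esrrb lines (0.0374 without OSCE 8 replicate 1, range 0.0374 to 0.269). A replicate block changed no call of a named gene or list and moved no count by over 1.5 times.
Counts fell where a 2-fold minimum was added, by construction: 3622 for MEFs against ES cells, 493 and 3325 for the Esrrb lines against ES cells and MEFs, 3653 for OSCK against MEFs, and against ES cells 562 (OSCK), 897 (OSCE 8), 650 (OSCE 13), 756 (OSE T8) and 668 (OSE T9). Among lines it left 311 for OSCE and 257 for OSE against OSCK, 279 for OSE against OSCE, 562 for OSCE 8 against OSCE 13, 262 for OSE T8 against OSE T9, and 460 between the MEF types. Of these, 65.4% were higher in OSE than OSCK (55.1% without the minimum) and 34.9% in OSCE 8 than OSCE 13 (47%). With lines as replicates, which leaves fewer samples, limma called 4833 (MEFs against ES cells), 97 and 6951 (Esrrb lines against ES cells and MEFs), 4812 (OSCK against MEFs), 3 (OSE against OSCE), and 0 for both OSCE and OSE against OSCK. With only the compared groups it called 1564 for OSE T9 against ES cells, 1234 for OSE against OSCK and 499 for OSE T8 against OSE T9. Without the OSE T9 line 3928 genes, and without the OSCE 8 line 3220, were called between Esrrb lines and ES cells.
Of 637 comparisons of a count, position or correlation with an alternative, 550 stayed within 1.5 times or 1 SD. Without 1 array, where the lone array is assumed to vary like the other groups, counts ran over 2133 to 3916 for Esrrb lines against ES cells (lowest without ES replicate 1 or 2), 1740 to 3020 for OSCK (OSCK replicate 2) and 2027 to 3539 for OSE T9 (ES replicate 2) against ES cells, 1178 to 2511 for OSCE (OSCK replicate 1; 1251 without replicate 2) and 1112 to 2427 for OSE against OSCK (OSCK replicate 2; 1161 without replicate 1). They ran over 1829 to 3287 for OSCE 8 against OSCE 13 (OSCE 8 replicate 2; 1884 without its replicate 1, 1866 and 1851 without OSCE 13 replicates 1 and 2), 957 to 2662 for OSE T8 against OSE T9 (OSE T8 replicate 2; 1189 without OSE T9 replicate 2) and 1129 to 2062 between MEF types (Pou5f1-GFP replicate 1; 1140 without Actin-GFP replicate 1). Positions ran over 0.111 to 0.128 (OSCK), 0.201 to 0.211 (OSCE 8), 0.101 to 0.114 (OSCE 13) and 0.122 to 0.135 (OSE T8); those that moved by more than the SD were all 4 without ES replicate 1, OSCE 13 and OSE T8 without ES replicate 2, and OSE T8 without Actin-GFP MEF replicate 2 (0.123) or Pou5f1-GFP MEF replicate 1 (0.122).
Positions moved by more than the SD of 2 arrays to these values: OSCE 8 0.196, OSCE 13 0.0998 without background correction; OSCE 8 0.207, OSCE 13 0.0969, OSE T8 0.122 with median centring; OSCK 0.104, OSCE 8 0.185, OSCE 13 0.0891, OSE T8 0.117 with the series matrix; OSCE 13 0.0990, OSE T8 0.121 with the filter of at least 8 arrays. The mean of probes gave OSCE 8 0.213, OSCE 13 0.109, OSE T8 0.134, and axis genes of at least 2-fold OSCE 8 0.201, OSCE 13 0.108, OSE T8 0.112. Over genes higher in MEFs alone the values were OSCK 0.136, OSCE 8 0.135, OSCE 13 0.123, OSE T8 0.183, OSE T9 0.238, and over genes higher in ES cells alone OSCK 0.102, OSCE 8 0.249, OSCE 13 0.0897, OSE T8 0.0859, OSE T9 0.145. Axis genes called toward MEFs numbered between 219 and 359 in OSCE 13 and between 317 and 504 in OSCE 8. Without the filter, which adds genes off in every group, correlations with ES cells were OSCK 0.987, OSCE 8 0.982, OSCE 13 0.986, OSE T8 0.985, OSE T9 0.986, and with MEFs OSCK 0.938, OSCE 8 0.943, OSCE 13 0.936, OSE T8 0.935, OSE T9 0.946.
Median centring moved the median of all genes to -0.14 for MEFs against ES cells and to 0.18 and 0.18 for Esrrb lines and OSCK against MEFs; with that shift, 60.3% of genes called between Esrrb lines and MEFs were higher, against 49.9%. In the series matrix, where background correction, normalization and the unit all differ, 53.6% of probes called between OSE T8 and OSE T9 were higher, against 43.3% of genes. No change can be seen in genes below background in both groups of a comparison.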

Other observations

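The tests of the interferon genes and the splits of whole lines were chosen only after the result was seen; the splits of single arrays were planned.
MEFs (n = 4 arrays) also differed from ES cells (n = 2 arrays) in genes of later lineages. The brain and skeletal transcription factor Zic1 (12.02-fold, 3.59 ± 0.10), the endoderm factor Gata6 (8.28-fold, 3.05 ± 0.12), the limb homeobox gene Msx1 (7.25-fold, 2.86 ± 0.12), the muscle regulator Mef2c (4.37-fold, 2.13 ± 0.097) and the imprinted growth regulator Dlk1 (19.9-fold, 4.31 ± 0.13) were higher in MEFs. The forebrain and epiblast factor Otx2 (at least 10.02-fold), the epiblast factor Pou3f1 (at least 23.1-fold), the trophoblast and germ cell factor Tfap2c (at least 59.7-fold), the placental imprinted gene Phlda2 (at least 20.0-fold), the germ line defence gene Tdrd12 (at least 27.4-fold) and the adhesion gene Pecam1 (at least 8.71-fold) were lower, with a largest adjusted p of 7.78e-11.
Among the lines, OSCE 13 had higher Rhox5 (5.43-fold, 2.44 ± 0.13), a homeobox gene of the germ line, Ct55 (at least 11.2-fold), a testis antigen, and Krt8 (5.50-fold, 2.46 ± 0.17) than ES cells. OSE T8 and OSE T9 differed in the cartilage collagen Col2a1 (4.65-fold, -2.22 ± 0.19) and the matrix gene Tnc (2.82-fold, -1.495 ± 0.15), both lower in OSE T8. OSCE 8 had lower Pecam1 (6.02-fold, -2.59 ± 0.12) than OSCE 13. Between the MEF types, the antigen-presenting H2-K1 (3.81-fold, 1.93 ± 0.33) was higher and the distal limb gene Hoxd13 (2.79-fold, -1.48 ± 0.24) lower in Actin-GFP MEFs. Each of these compared groups of n = 2 arrays, and no adjusted p exceeded 0.000961.
Interferon and antigen presentation genes were lower than in ES cells in all 5 lines, at medians from -1.64 (OSCK) to -1.08 (OSCE 8). The slide is argued against, as OSCK and OSCE 8 shared slides with the ES cells and the highest median within a slide was -1.05. RNA of fibroblasts like the measured MEFs in the ES cultures is argued against as well. The list was lower in both MEF types than in ES cells, at -0.68 (Actin-GFP) and -1.20 (Pou5f1-GFP). The mitomycin C-treated feeders were not measured as a group of their own, so RNA of treated feeders stays open. The list was lower in the lines than in MEFs too, at -0.51 (adjusted p = 0.00409, 0.116 with an estimated correlation) for the Esrrb lines and -0.73 (adjusted p = 0.000164, 0.067 with an estimated correlation) for OSCK. MEFs are another cell type, and these calls are lost with an estimated correlation. A higher interferon response of the ES line or its culture, and a lower one of the iPS lines, cannot be told apart, because there is 1 ES line.
Other splits of the arrays did not give as many called genes as the real ones. For Esrrb lines against MEFs (12 arrays), 1 of 100 splits drawn from 495, the real one, called as many as 9099 genes, and the highest of the others called 22. For OSE against OSCE (8 arrays), 1 of 35 splits, the real one, called as many as 696, and the highest of the others called 81. These fits hold only the arrays of the 2 groups compared and no term for the line, so their counts are lower than those of the whole design. Most splits break up the lines and so mix differences between lines into both sides. Splits that keep lines and MEF types whole number 15 for Esrrb lines against MEFs, where the highest of the others called 292, and 3 for OSE against OSCE, where the others called 81 and 32; both are too few for a share under 0.05. With lines as replicates, a fit with 3 residual degrees of freedom, limma called 6951 genes between Esrrb lines and MEFs. This argues against chance as the source of that count. Between OSE and OSCE it called 3, with 1411 at an unadjusted p under 0.05.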
